A study of Mus musculus with 4 samples.

How the data were processed

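Liver RNA of 4 male mice, 1 per genotype, was profiled by RNA sequencing; per the labels' protocols, tissue was stored in RNAlater, RNA was extracted with Qiagen RNeasy, and libraries were made with the TruSeq RNA Library Prep Kit v2. The groups WT, Cyp27a1 KO, Cyp3a KO and DKO were taken from the genotype and title labels. The submitters' processing notes name Trimmomatic 0.33, HISAT2 2.0.5, kallisto 0.43.1 and the mm10 build without saying what each was used for; the annotation release and the rule for summing transcripts to genes are not given in the sources used here. The notes name both a genome aligner and a pseudo-aligner, so which of them gave the deposited values is open.

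The authors deposited estimated counts per gene symbol, not scaled to a common total, of which 57.7% were whole numbers; they were rounded to whole numbers before use. 3 values above 1000000 carried 3 significant digits. The authors also deposited transcript abundance scaled to a fixed total (TPM), used here as an alternative and for comparison with the counts. Columns stand in a different order in the 2 tables and were matched by name: deviations from the gene mean correlated at 0.941 to 0.974 between the tables for libraries of the same name and at most 0.0237 otherwise. 1 row that names no gene held 0 counts and was left out. Of 33639 genes, 32114 matched 1 gene of GENCODE release M21 (GRCm38, the mm10 build) by symbol, which gave the coordinates. Alb took 3.78% to 7.08% of the counts of a library and mitochondrial genes 5.53% to 7.32%.

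Counts were scaled with TMM factors (edgeR 4.0.16 in R 4.3.3), which were 0.937, 0.996, 0.994 and 1.08 in the order of the groups above. Log2 folds are of CPM plus a pseudocount of 0.5, which understates the folds of low genes, while fold ratios in the text are of CPM without it. As there is 1 library per genotype, no test across genes was run. A gene was called higher or lower where its log2 fold was at least 2-fold in size, its mean CPM over the 4 libraries was at least 1, and the exact 95% interval of the count ratio (Clopper-Pearson, conditional binomial) excluded 1. Intervals of single counts are exact Poisson. A count of 0 was given the floor of 3 counts for bounds. Reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. An additive model that takes the departure from additivity as error was not run.

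The rule was tested on simulated data with 50 genes altered at each of 4 known folds, drawn from the real mean profile and library sizes. For the Cyp27a1 KO against WT, with counting error alone, 96.0% of 50 genes altered 3-fold and 100% of 50 altered 8-fold were called the right way, 0 of 50 altered 1.5-fold were called, and 0 of 11533 unaltered genes were called. With an assumed between-animal coefficient of variation of 0.2 in place of a measured one, 84.0% of genes altered 3-fold and 157 of 11543 unaltered genes were called in that comparison, 144 of 11538 in the Cyp3a KO against WT, and 130 of 11532 in the DKO against WT.

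The 5 comparisons were each knockout against WT and the DKO against each single knockout. Loss of each gene was measured in 2 pairs of libraries with no library in common; the overlap of calls was set beside n1 × n2 / N, and correlations across genes carry no p-value. The 40 gene lists, the calling rule, the alternatives and the rule for named genes were fixed before the data were examined. A list's median log2 fold over its measured members was placed among the medians of 10000 random lists of the same size matched on mean CPM in 20 bins, as a description of these libraries. The lists of T and NK cells and of nuclear RNAs had 0 measured members.

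The genes named are the measured members of the bile acid synthesis and Cyp3a lists; in each comparison with WT the 8 largest and 8 smallest log2 folds among called genes with a mean CPM of at least 5; for each loss the 6 largest and 6 smallest values of the fold nearest 0 among genes called the same way in both pairs; and up to 4 members per other list with the largest folds. Symbols of predicted genes were passed over, at most 5 per direction. Some were left out for length, and members that show a list's range or its low end are named as such; genes named outside the rule are said to be chosen after their values were seen.

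Alternatives were library-total scaling, median-of-ratios scaling (DESeq2 1.42.0), the deposited TPM in place of counts, no filter, a mean CPM of at least 5, pseudocounts of 0.1 and 2, a 4-fold rule, and no counting interval. TPM recentred on the median gene was added after seeing the data. Computation used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.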

Results

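The series asked how global loss of Cyp27a1 and of the Cyp3a genes alters bile acid synthesis in mouse liver. TruSeq RNA libraries were made from the liver of 1 male mouse per genotype, giving 4 libraries: wild type (WT), Cyp27a1 knockout (KO), Cyp3a KO, and the double knockout of both (DKO). The mice were chow-fed and otherwise untreated. The submitters' labels name the deleted gene by the human symbol Cyp3a4, whereas the mouse carries a family of Cyp3a genes, and the family is reported here. The deposited tables held estimated counts and TPM for 33639 genes, with totals of 49745860 counts in WT, 49980012 in the Cyp27a1 KO, 50378101 in the Cyp3a KO and 50280651 in the DKO. At these depths 11743 genes had a mean of at least 1 CPM (counts scaled to a library total of 1000000), and 1 count was worth between 0.0185 and 0.0214 CPM. With 1 library per genotype no difference below has a replicate check, so no p-value is given and every statement compares these libraries rather than the genotypes. Intervals in parentheses after a fold are exact 95% intervals of the count ratio and cover counting error only.

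The targeted genes followed the labels. Cyp27a1, the mitochondrial sterol 27-hydroxylase of the acidic bile acid pathway (chromosome 1, 74713574 to 74737892, mm10), stood at 746 CPM in WT and 727 CPM in the Cyp3a KO. It stood at 57.6 CPM (exact Poisson interval 55.6 to 59.8) in the Cyp27a1 KO and at 65.3 CPM (63.2 to 67.5) in the DKO, so 7.73% and 8.75% of the WT level of transcript counts remained. Cyp3a11, the most abundant hepatic Cyp3a (chromosome 5, 145854426 to 145879964), stood at 8742 CPM in WT and 23706 CPM in the Cyp27a1 KO. It was 0.160 CPM (0.0690 to 0.315) in the Cyp3a KO and 4.76 CPM (4.20 to 5.38) in the DKO. Summed over the family, Cyp3a counts were 9605 CPM in WT, 25248 CPM in the Cyp27a1 KO, 2.70 CPM in the Cyp3a KO and 13.2 CPM in the DKO.

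Of the Cyp3a counts left after Cyp3a deletion, Cyp3a13 (chromosome 5, 137892932 to 137921619, outside the main cluster) supplied 122 in the Cyp3a KO and 143 in the DKO, both under 3% of its WT CPM. Cyp3a25 had 0 counts in the Cyp3a KO, which allows up to 0.0599 CPM, and 19 in the DKO, against 31582 in WT. Cyp3a41a was the exception: it had 292 counts in the DKO, 99 in WT and 5 in the Cyp3a KO. Cyp3a16 and Cyp3a41b had 0 counts in both Cyp3a-deleted libraries, and Cyp3a44 had 0 and 2. These genes are near-identical in sequence, so the split of counts among them is uncertain.

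**Figure D1:**
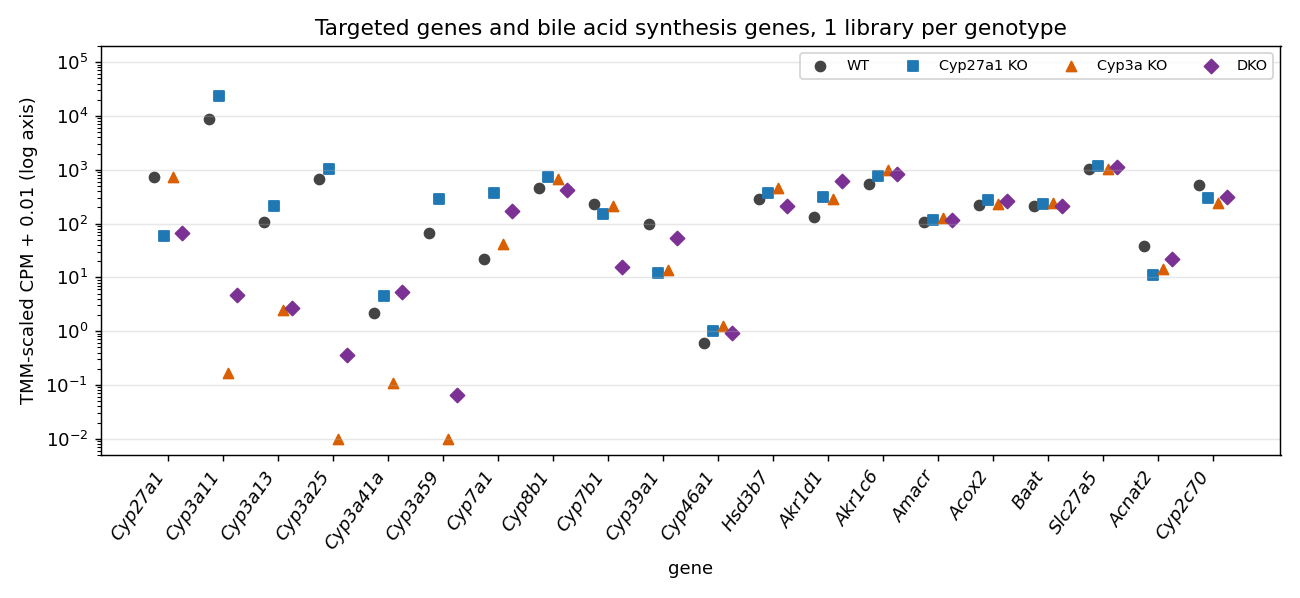
TMM-scaled CPM plus 0.01 on a log axis for the targeted genes and 14 bile acid synthesis genes, with 1 point per library (WT, Cyp27a1 KO, Cyp3a KO and DKO) and no error bars because each genotype has 1 library. Cyp27a1 is at 57.6 and 65.3 CPM in the 2 libraries in which it was deleted, and Cyp7a1 is at its highest in the Cyp27a1 KO, at 362 CPM.

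In the liver without Cyp27a1, Cyp7a1, the rate-limiting enzyme of the classic bile acid pathway (chromosome 4, 6265612 to 6275633), was 16.2-fold higher (15.2 to 17.2) than in WT. The Cyp3a family was higher as well, with 6 of 8 measured members at least 2-fold above WT, a list median log2 fold of 1.26 and percentile 100 among 10000 random lists matched on expression. Cyp3a11 was 2.71-fold higher (2.70 to 2.72) and Cyp3a59 was 4.19-fold higher (4.03 to 4.35). As the split of counts among near-identical Cyp3a genes is uncertain, the 6 may not be separate observations. Targets of the xenobiotic receptors PXR and CAR outside the Cyp3a family were higher in 13 of 23 cases and lower in 0, with a median log2 fold of 1.39 (percentile 100). In total 287 genes were at least 2-fold higher and 160 at least 2-fold lower in the Cyp27a1 KO than in WT.

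Within the 18 measured bile acid synthesis genes, 2 were at least 2-fold higher and 3 lower in the Cyp27a1 KO. Akr1d1, the steroid 5-beta-reductase, was 2.38-fold higher (2.31 to 2.45). Cyp39a1, the 24-hydroxycholesterol 7-alpha-hydroxylase, was 8.29-fold lower (7.61 to 9.04), and Acnat2, an acyl-CoA amino acid N-acyltransferase, was 3.44-fold lower (3.12 to 3.79). Cyp8b1, the sterol 12-alpha-hydroxylase, had a log2 fold of 0.67 and Cyp7b1 one of -0.62, below the 2-fold rule. Nr0b2 (SHP), a bile-acid-induced repressor, was 2.07-fold lower (1.83 to 2.35), the 1 of 5 measured FXR targets past the rule, with a log2 fold of -1.01 that was -0.85 on deposited TPM, outside the rule; the list median was -0.23 (percentile 4.71). Of 14 transport genes 3 were higher and 1 lower, with Abcc4, a basolateral exporter, 6.99-fold higher (5.90 to 8.34) and Slco1a1, a sinusoidal uptake carrier, 4.37-fold lower (4.22 to 4.52).

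The largest folds in the Cyp27a1 KO were in conjugating and detoxifying enzymes. Sult2a7 was 86.4-fold higher (60.0 to 129), Gstm3 29.5-fold higher (28.3 to 30.7), Gsta1 19.5-fold higher (17.0 to 22.5) and Cyp2c55 25.9-fold higher (23.5 to 28.6). Of 23 phase II conjugation genes 9 were higher and 2 lower (median 0.55, percentile 100), and 5 of 11 NRF2 targets were higher, among them Nqo1, 4.22-fold higher (3.42 to 5.25), although Gsta1, Gsta2, Gstm1 and Gstm3 stand in several of these lists. Fam19a2, Robo1 and Pls1 were also among the 8 largest once predicted genes were passed over, with log2 folds of 4.10, 3.13 and 3.35. The Sult2a, Gsta, Gstm and Cyp2c genes belong to families that share reads, so values of single members are uncertain.

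Cholesterol synthesis and uptake genes, the targets of SREBP2, were at least 2-fold higher in 11 of 25 cases in the Cyp27a1 KO (median 0.91, percentile 100). Fdps was 3.44-fold higher (3.35 to 3.54) and Idi1 3.34-fold higher (3.21 to 3.47). Of 15 lipogenic genes 5 were higher, including Elovl6 (4.09-fold higher (3.80 to 4.40)) and Scd1 (2.58-fold higher (2.57 to 2.59)). Of 22 PPARalpha targets and fatty acid oxidation genes 5 were lower and 1 higher (median -0.57, percentile 0): Cyp4a14 was 6.72-fold lower (6.61 to 6.83), Cyp4a31 7.87-fold lower (7.04 to 8.82) and Fgf21 10.1-fold lower (6.09 to 17.7), whereas the fatty acid transporter Cd36 was 6.22-fold higher (5.83 to 6.65). Major urinary protein genes and the iron hormone gene Hamp were among the lowest, with Mup7 7.68-fold lower (7.65 to 7.72), Mup8 8.41-fold lower (7.24 to 9.81), Serpine2 8.43-fold lower (6.93 to 10.3) and Hamp 5.73-fold lower (5.57 to 5.90). Summed over 21 near-identical Mup genes, CPM was 0.420 of the WT value, a smaller drop, so folds of single Mup genes are uncertain.

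Markers of other cells were compared between the Cyp27a1 KO and WT libraries as well. Kupffer cell markers had a median log2 fold of 0.07 with 0 of 12 past the rule, endothelial markers -0.27 with 0 of 9, stellate and matrix genes -0.30 with 1 of 12 higher (0 on deposited TPM), and cholangiocyte markers -0.54 with 2 of 6 lower (0 on deposited TPM). The stellate gene not called on deposited TPM, Acta2, kept a log2 fold of 1.02 there, but its mean was below the filter. Erythroid genes had a median of -0.75 (percentile 0) with 1 of 5 lower, and 0 on deposited TPM. On the deposited TPM, which moved the median gene by 0.18, the split of 287 higher and 160 lower genes (64.2% higher) became 446 and 129 (77.6%). Counts called on 1 animal per genotype include any difference between individual mice.

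In the liver without Cyp3a, cholesterol synthesis genes and xenobiotic receptor targets stood above WT. Of 25 cholesterol synthesis and uptake genes, 18 were at least 2-fold higher and 0 lower (median log2 fold 1.29, percentile 100), led by Idi1 (6.30-fold higher (6.07 to 6.54)), Fdft1 (4.69-fold higher (4.46 to 4.94)) and Hmgcs1 (4.61-fold higher (4.48 to 4.74)). PXR and CAR targets were higher in 14 of 23 cases and lower in 1 (median 1.47, percentile 100), with Cyp2c55 48.5-fold higher (44.2 to 53.5) and Gstm3 29.3-fold higher (28.1 to 30.5). All 8 measured Cyp3a genes were lower, as set out above, and 301 genes in all were higher and 219 lower.

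Bile acid synthesis genes past the rule in the Cyp3a KO were 1 higher and 3 lower of 18. Akr1d1 was 2.17-fold higher (2.11 to 2.24), Cyp39a1 7.44-fold lower (6.86 to 8.08), Acnat2 2.68-fold lower (2.45 to 2.93) and Cyp2c70, which makes muricholic acids in mice, 2.13-fold lower (2.09 to 2.18); on the deposited TPM the log2 fold of Cyp2c70 was -0.99, just outside the rule. Cyp7a1 was 1.85-fold higher (1.71 to 1.99) by counts, under the rule, but its TPM gave a log2 fold of 1.64 against 0.87 by counts. Nr0b2 was 2.84-fold higher (2.61 to 3.08), opposite to its direction in the Cyp27a1 KO, and Abcc3 and Slco1a4 were 3.51-fold higher (3.43 to 3.59) and 3.43-fold higher (3.32 to 3.55).

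Of the genes higher in the Cyp3a KO, the largest fold was that of AW822252, annotated as a transcribed pseudogene on chromosome X (53695855 to 53716773), which had 131 counts in WT, 89 in the Cyp27a1 KO, 48252 in the Cyp3a KO and 33089 in the DKO. Sult2a7 was 110.2-fold higher (76.6 to 165), Nebl, encoding nebulette, 108-fold higher (69.7 to 177), Cyp2c69 50.5-fold higher (36.5 to 71.9), Cyp2c40 24.4-fold higher (21.8 to 27.4) and the guanylate-binding protein gene Gbp10 17.8-fold higher (13.2 to 24.6). Outside the Cyp3a family the lowest were Fam107a (13.8-fold lower (11.7 to 16.2)), the steroid 17-alpha-hydroxylase gene Cyp17a1 (10.2-fold lower (8.53 to 12.4)) and the cell cycle inhibitor gene Cdkn1a (7.50-fold lower (7.08 to 7.96)). Predicted genes, some of them lower still, were passed over in this ranking.

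Clock genes also stood apart in the Cyp3a KO library. Of 16 measured, 3 were higher and 3 lower: Dbp was 14.0-fold higher (11.4 to 17.5), Nr1d1 10.5-fold higher (9.70 to 11.4) and Bhlhe41 30.3-fold higher (15.1 to 70.8), while Cry1 was 5.79-fold lower (5.16 to 6.52), Npas2 6.59-fold lower (4.64 to 9.60) and Arntl 2.80-fold lower (2.53 to 3.10). On deposited TPM 2 were higher and 2 lower, as Bhlhe41 and Npas2 had a mean below the filter there. The difference between the median of 7 genes of the Dbp phase and 5 genes of the Arntl phase was 2.34 on the log2 scale, against -0.20 in the Cyp27a1 KO. These genes were chosen from the 16 after the results were seen. Left out were Bhlhe41 (log2 fold 3.083 in the Cyp3a KO), Cry2 (0.183), Per1 (-0.215) and Hlf (-0.301). PPARalpha targets were lower in 8 of 22 cases and higher in 1 (median -0.47, percentile 0), with Cyp4a14 3.76-fold lower (3.71 to 3.81) and Pdk4 3.72-fold lower (3.42 to 4.05). Of 12 immediate early and heat shock genes 8 were higher (median 1.16, percentile 100), including Egr1 (6.13-fold higher (5.66 to 6.65)), which was also 8.02-fold higher (7.42 to 8.68) in the Cyp27a1 KO; both folds rest on the same WT library. The list also stood above that library in the Cyp27a1 KO, with 3 higher and 0 lower (median 0.48, percentile 99.98), and in the DKO, with 8 higher and 1 lower (median 1.13, percentile 100). Kupffer markers had a median of -0.57 (percentile 0), with Marco 3.28-fold lower (2.57 to 4.22), and 4 of 5 erythroid genes were lower, Hba-a1 being 3.09-fold lower (2.92 to 3.28).

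In the liver without either gene the differences from WT were wider, with 705 genes at least 2-fold higher and 472 lower. Cholesterol synthesis and uptake genes were higher in 23 of 25 cases and lower in 0 (median log2 fold 2.60, percentile 100), with Idi1 16.6-fold higher (16.0 to 17.2) and Hmgcs1 13.3-fold higher (12.9 to 13.7). PXR and CAR targets were higher in 19 of 23 cases (median 2.86, percentile 100), including Gstm3 (140.0-fold higher (134 to 146)) and Cyp2c55 (108-fold higher (98.6 to 119)). Genes with male-biased hepatic expression were lower in 11 of 15 cases and higher in 0 (median -2.70, percentile 0), and female-biased genes were higher in 8 of 10 and lower in 2 (median 3.82, percentile 100). In the Cyp27a1 KO 4 male-biased genes were lower and 2 higher (median -0.50, percentile 0), and 4 female-biased genes were higher and 2 lower (median 0.03). In the Cyp3a KO these numbers were 2 and 2 (median 0.10), and 2 and 3 (median -0.32, percentile 0.35). Cell cycle genes were higher in 11 of 15 cases (median 1.58, percentile 100). The filter uses the mean over the 4 libraries, so genes high in the DKO alone, such as Ccnb1, Cdc20 and Cyp2b9, were measured through that library. The shares called higher in the cell cycle and female-biased lists are therefore partly set by the filter. Cyp2b9 and Cyp2b13 (log2 folds 6.87 and 6.12) stand in both the female-biased list and the PXR and CAR list. They count as higher in both lists in each comparison of the DKO, so these lists are not fully separate. Of 14 female-biased genes fixed, 10 were measured.

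Sulfotransferase and major urinary protein genes were among the largest folds in the DKO. The sulfotransferase genes Sult2a1, Sult2a2 and Sult2a5 had 39439, 32219 and 6907 counts against 119, 100 and 22 in WT, and Cyp2b9 was 311-fold higher (185 to 568). In the other direction, Mup7 was 1632-fold lower (1530.4 to 1742), Mup1 215-fold lower (194 to 238), Mup11 162-fold lower (156 to 168), Mup15 214-fold lower (201 to 228), Elovl3 168-fold lower (148 to 190.3), Slco1a1 176-fold lower (145 to 215) and Hamp 457-fold lower (365 to 581). Summed over 21 Mup genes, CPM in the DKO was 0.0267 of the WT value, against 0.420 in the Cyp27a1 KO and 0.874 in the Cyp3a KO. Mup8 had 0 counts in the DKO and was at least 594-fold lower than in WT. Cyp7b1, the oxysterol 7-alpha-hydroxylase and itself male-biased, was 15.1-fold lower (14.0 to 16.2).

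Bile acid synthesis genes otherwise showed 2 of 18 higher and 2 lower. Cyp7a1 was 7.75-fold higher (7.27 to 8.27) and Akr1d1 4.75-fold higher (4.62 to 4.88), the lower pair being Cyp7b1 and the deleted Cyp27a1. The list median of -0.30 was 0.06 on deposited TPM, so its sign depends on the table used. Deposited TPM also moved the median of all genes to 0.33, a shift of about the same size. Cyp8b1 and Cyp39a1 had log2 folds of -0.15 and -0.91. Of 14 transport genes 6 were higher and 1 lower, with the sterol exporters Abcg5 and Abcg8 3.04-fold higher (2.92 to 3.17) and 2.89-fold higher (2.79 to 2.98), Abcc4 6.38-fold higher (5.38 to 7.62) and Abcb1a 8.63-fold higher (7.19 to 10.4). Of 15 lipogenic genes 7 were higher, among them Acly (4.38-fold higher (4.23 to 4.53)) and Elovl6 (8.35-fold higher (7.79 to 8.95)), and PPARalpha targets were lower in 11 of 22 cases and higher in 1 (median -1.06, percentile 0), with Cyp4a14 18.8-fold lower (18.4 to 19.3) and Acot1 6.10-fold lower (5.80 to 6.41).

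Other cells and states differed in the DKO library too. Cyclins and mitotic genes such as Cdc20 (389 counts against 13 in WT), Ccnb1 (286 against 9) and Mki67 (430 against 33) were higher. On deposited TPM 8 of 10 measured cell cycle genes were higher, and Mki67 had a mean below the filter. Interferon response genes were higher in 10 of 15 cases (median 1.24, percentile 100), with Oasl1 4.46-fold higher (3.59 to 5.59) and Ifit1 4.35-fold higher (3.44 to 5.56); Kupffer markers were higher in 2 of 12 (median 0.62, percentile 99.97), or 4 of 12 on deposited TPM, with Adgre1 2.63-fold higher (2.40 to 2.89) and Cd5l 2.25-fold higher (2.14 to 2.36). Erythroid genes were lower in 4 of 5 cases (median -1.16), but in 1 of 5 on deposited TPM (median -0.80). The clock contrast was 4.17, with Dbp 24.3-fold higher (19.8 to 30.1) and Arntl 15.0-fold lower (12.3 to 18.4). Under library-total scaling, which moved the median gene by 0.17, the split of 705 higher and 472 lower (59.9% higher) became 975 and 356 (73.3%), and on deposited TPM, which moved it by 0.33, 1280 and 268 (82.7%).

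**Figure D2:**
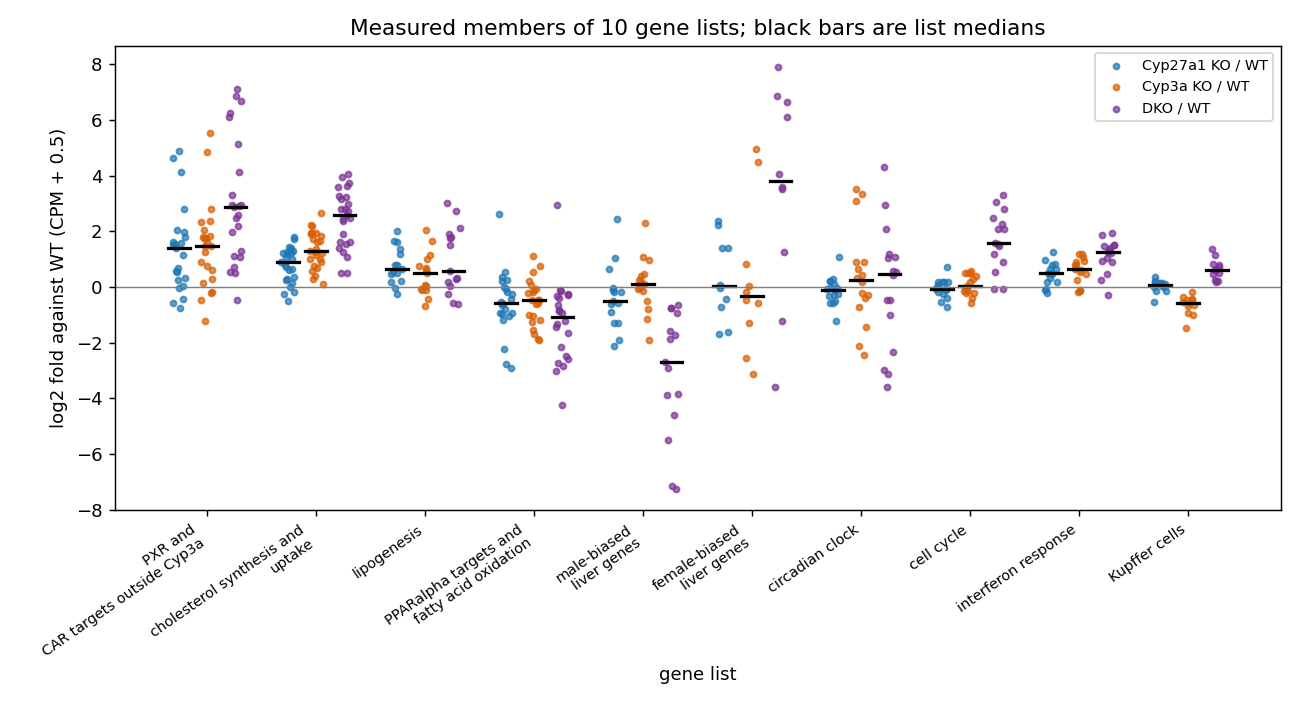
Log2 fold against WT, on CPM plus 0.5, of each measured member of 10 gene lists, with 1 point per gene, 1 colour per knockout library and black bars at the list medians. The cholesterol synthesis medians are 0.91, 1.29 and 2.60 in the Cyp27a1 KO, Cyp3a KO and DKO, and the male-biased median in the DKO is -2.70.

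Because the genotypes form a square, loss of each gene was measured in 2 pairs of libraries with no library in common. For Cyp27a1, the pairs were the Cyp27a1 KO against WT and the DKO against the Cyp3a KO, where 472 genes were higher and 317 lower. In both pairs 116 genes were higher, against 11.5 for independent lists, and 62 were lower, against 4.32; 16 were higher and then lower, against 7.75, and 12 lower and then higher, against 6.43, so opposite directions also exceeded independence. Higher in both were Fam19a2 (log2 folds 4.10 and 3.46), Gsta1 (4.15 and 3.43), the class I gene H2-Q1 (3.11 and 3.77), the proton pump subunit gene Atp6v0d2 (2.96 and 4.13), Lrtm2 (2.93 and 5.39), the serine protease gene Prss8 (2.98 and 2.75), Cyp7a1 (3.99 and 2.06) and Abcc4 (2.63 and 2.44). Lower in both, besides Cyp27a1, were Mup7 (-2.94 and -10.16), Mup8 (-2.92 and -4.55), Mup1 (-2.33 and -7.39), Hamp (-2.51 and -7.16) and Cyp4a14 (-2.75 and -2.32). Across genes, which are not independent replicates, the folds had Pearson's r of 0.355 and Spearman's rho of 0.302. PXR and CAR targets were higher in 10 of 23 cases and cholesterol genes in 16 of 25 in the DKO against the Cyp3a KO, with medians of 0.89 and 1.14, while 14 of 15 male-biased genes were lower. On deposited TPM the split of the second pair, 59.8% higher, became 77.7%.

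For Cyp3a the pairs were the Cyp3a KO against WT and the DKO against the Cyp27a1 KO, where 333 genes were higher and 304 lower. In both pairs 89 genes were higher, against 8.54 for independent lists, and 68 were lower, against 5.67, while 28 were higher and then lower, against 7.79, and 15 lower and then higher, against 6.21. Higher in both were AW822252 (log2 folds 8.19 and 8.06), Dbp (3.52 and 4.87), Hsd17b6, a hydroxysteroid dehydrogenase gene (2.48 and 2.83), Idi1 (2.65 and 2.31), Fdft1 (2.22 and 2.24) and Gstm3 (4.86 and 2.25). Lower in both, besides Cyp3a11, Cyp3a13, Cyp3a25 and Cyp3a59, were Cdkn1a (-2.88 and -3.97) and the ferritin receptor gene Scara5 (-2.43 and -5.11). Across genes r was 0.341 and rho 0.241, and r was 0.266 without the targeted genes. In the DKO against the Cyp27a1 KO, 19 of 25 cholesterol genes and 12 of 23 PXR and CAR targets were higher, with medians of 1.44 and 1.11, and Cyp7a1 was 2.09-fold lower (2.04 to 2.14). The clock contrast was 5.02 in that pair and 1.59 in the DKO against the Cyp3a KO, so it was not matched between the libraries of either pair. In the Cyp3a KO against WT it was 2.34, so both Cyp3a pairs carried a clock difference of the same sign. The lack of a shared library therefore does not keep genes that go with that difference out of the overlap. On deposited TPM the split of 52.3% higher in the second pair became 65.6%.

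**Figure D3:**
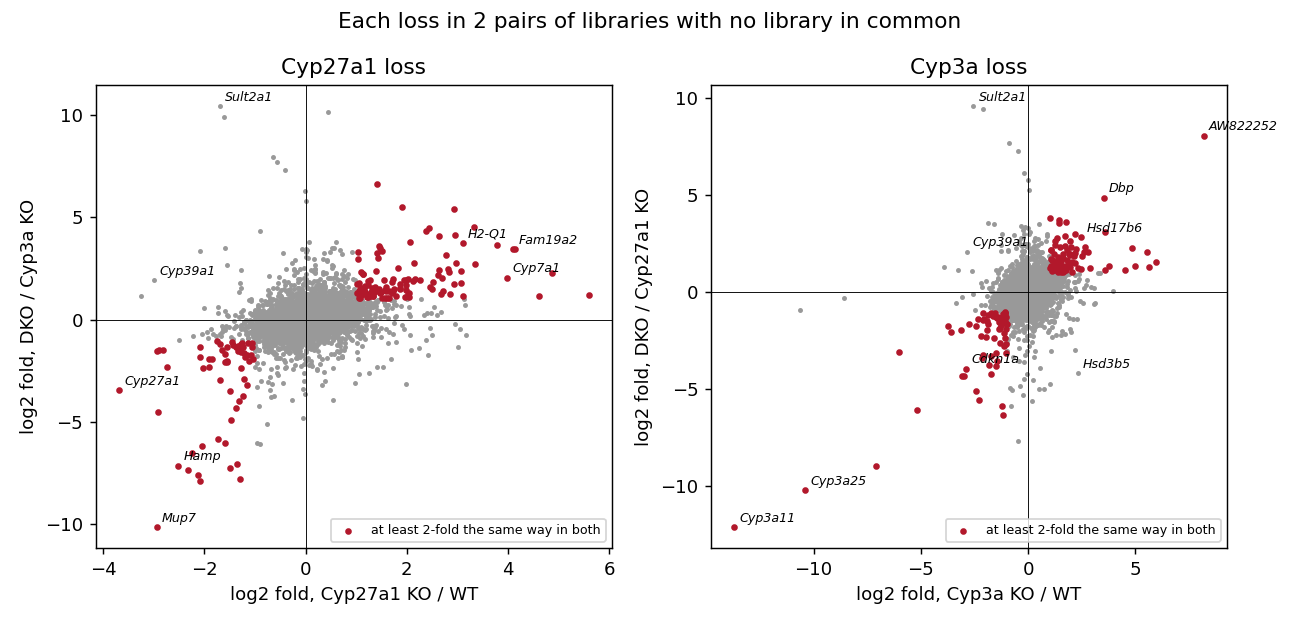
Log2 fold of each of 11743 measured genes in the 2 library pairs that differ in Cyp27a1 (left) and in the 2 that differ in Cyp3a (right), with genes at least 2-fold apart the same way in both pairs in red. The 116 genes in the upper right and 62 in the lower left of the Cyp27a1 panel, and 89 and 68 in the Cyp3a panel, are those past the rule in both pairs.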

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

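Named genes past the 2-fold rule in opposite directions in the 2 separate pairs for the same loss were picked out; these differences were not tested, since each pair is 1 library against 1. The tests of sex-biased genes and of collection time below were chosen after the results were seen. Sult2a1 was lower in the Cyp27a1 KO than in WT (log2 fold -1.70) and higher in the DKO than in the Cyp3a KO (10.45), a difference of 12.15. For Cyp3a loss (-2.55 and 9.60) the difference is the same by arithmetic, as both use the same 4 libraries. This holds for every gene, so a match between the losses is not a second observation. Sult2a2 differed by 11.53 (-1.62 and 9.91 for Cyp27a1 loss, -2.09 and 9.43 for Cyp3a loss). Cyp39a1 differed by 4.94, being lower in each single knockout than in WT (-3.00 and -2.85) and higher in the DKO than in the single knockouts (1.94 and 2.09). Cyp2c69 differed by -3.63 and Nebl by -4.37 for Cyp27a1 loss, higher in the Cyp27a1 KO than in WT (2.24 and 3.01) and lower in the DKO than in the Cyp3a KO (-1.40 and -1.36); on deposited TPM the last value of Nebl was -0.98, outside the rule. For Cyp27a1 loss, Bhlhe41 differed by -3.71 (1.06 and -2.65) and Apoa4 by 2.68 (-1.32 and 1.36). For Cyp3a loss, Hsd3b5 differed by -6.49 (2.31 and -4.18), Vnn1 by -2.94 (1.12 and -1.82), Marco by 2.63 (-1.48 and 1.16) and Asns by -2.41 (1.20 and -1.22). For both losses, Moxd1 differed by -4.14, Apcs by -2.59 and Acta2 by -2.18, each higher in the single knockouts than in WT and lower in the DKO than in the single knockouts. On deposited TPM none of Bhlhe41, Moxd1 and Acta2 was past the rule in these pairs, as their mean was below the filter there. Some of their folds stayed above 2-fold. Moxd1 was at 1.81 in the Cyp27a1 KO against WT and at -2.10 in the DKO against the Cyp27a1 KO. Acta2 was at 1.02 and 1.11 in the single knockouts, and Bhlhe41 at -1.48 in the DKO against the Cyp3a KO. Their other folds in these pairs were below 2-fold.

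Sult2a1 belongs to a wider pattern, lower male-biased and higher female-biased genes in the DKO; in the Cyp27a1 KO 4 of 15 male-biased genes were lower and 2 higher, and the female-biased median was 0.03. A female liver under the DKO label is argued against by the Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d. For each, CPM in the DKO was divided by its mean in the other libraries, and the median of these ratios was 1.12. Reads moving among near-identical Mup genes are argued against by their sum, which was 0.0267 of WT. Secreted hepatocyte proteins argue against a lower share of hepatocytes as the whole cause of the lower male-biased genes. The lowest of these proteins was at -1.173, against a male-biased median of -2.70. That comparison was added after the comparison of medians had been undecided and the values had been seen. As part of the cause, a lower share cannot be told apart from genotype. The medians lay 2.452 apart, but the gene-bootstrap interval of 0.790 to 3.782 reaches below the mark of 1. An effect of genotype and a trait of this 1 mouse both stay open and untested.

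Clock and cholesterol synthesis genes stood apart together in the Cyp3a KO and DKO libraries. Collection at another time of day could account for the clock genes: the contrast of the opposite phases against WT was 2.341 in the Cyp3a KO and 4.167 in the DKO. No collection time is in the labels used here, so time of day and genotype cannot be told apart for the clock genes. The same holds for the cholesterol genes of the Cyp3a KO, where the same 2.341 applies. It holds as well for the cholesterol genes of the DKO, where the contrast was 4.167 and the cholesterol median 2.603. No separate test was run for those. For the Cyp27a1 KO the contrast was -0.201 while the cholesterol median was 0.906, which argues against time of day as the cause there. An effect of genotype on cholesterol synthesis stays open in all 3 knockout libraries, untested beyond 1 mouse each.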

How the results depend on the processing

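TPM recentred on the median gene, and the count of genes past the rule in both pairs under any alternative, were added after seeing the data. Median-of-ratios scaling, library-total scaling, no filter and a pseudocount of 0.1 left the counts of genes within 1.5 times the main count. These 4 also left both correlations inside their gene-bootstrap intervals. Leaving out the counting interval changed no count of genes, so that criterion had removed no gene, and it does not enter a correlation. With the deposited TPM, genes higher were 446 (Cyp27a1 KO against WT), 1280 (DKO against WT) and 736 (DKO against Cyp3a KO), and genes lower 268 and 211 in the latter pair of comparisons; 192 genes were higher with Cyp27a1 loss in both pairs and r was 0.3103 for that loss. TPM moved the median gene by 0.18, 0.33 and 0.24 in these comparisons: once recentred, the counts were 323, 714 and 475 higher and 431 and 303 lower, with 123 in both pairs. Recentring left r at 0.3142, below its gene-bootstrap interval of 0.3151 to 0.395, and the cause of that difference was not tested. A mean CPM of at least 5, which leaves fewer genes, gave 98 lower in the Cyp27a1 KO and 132 lower in the Cyp3a KO than in WT, and 454, 269 and 181 higher in the DKO than in WT, the Cyp3a KO and the Cyp27a1 KO. A pseudocount of 2, which shrinks low genes, gave 96 and 132 lower in the single knockouts, 311 higher in the DKO than in the Cyp3a KO, and 76 higher and 41 lower with Cyp27a1 loss in both pairs. The 4-fold rule gave 65 higher and 23 lower (Cyp27a1 KO), 51 and 38 (Cyp3a KO), 197 and 114 (DKO), 108 and 84 (DKO against Cyp3a KO) and 91 and 79 (DKO against Cyp27a1 KO), with 23 and 11 in both pairs for Cyp27a1 loss and 13 and 14 for Cyp3a loss. The number of genes called within a list differed between counts and deposited TPM in 54 of 114 cases of a list against WT. Of the list medians outside the central 95% of random lists, 3 changed sign on deposited TPM: lipoproteins (-0.16 to 0.0123) and acute phase (-0.12 to 0.0582) in the Cyp27a1 KO against WT, and immediate early genes (-0.29 to 0.0206) in the DKO against the Cyp3a KO. None of the 3 changed sign once TPM was recentred on the median gene, so these changes go with the shift of all genes. They were not traced gene by gene. Values under an alternative were checked for named genes, except members named only from the other lists and genes chosen after their values were seen. Of these values, 1582 stayed inside their counting interval, 1098 moved outside it and 0 called folds changed sign. Where that interval had no upper end, a fixed limit on the shift was used instead. For list medians the numbers were 847, 470 and 3, the last among medians outside the central 95% of random lists only. No paired analysis was possible because each genotype has 1 library and the labels carry no replicate numbers; for the same reason no library could be left out.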

Other observations

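No test in this part was chosen only after its result was seen: the test of genes near the deleted loci was written beforehand, and the other values are descriptive.

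Of 14 ER stress genes, 5 were higher and 1 lower in the Cyp3a KO against WT (median 0.52, percentile 99.99), with Trib3 4.85-fold higher (4.19 to 5.65) and Sdf2l1 2.05-fold higher (1.86 to 2.25), against 1 higher in the Cyp27a1 KO (median 0.02) and 2 higher and 1 lower in the DKO (median -0.14). Gdf15, a stress-induced cytokine gene, was 4.61-fold higher (4.41 to 4.82) in the Cyp3a KO. The ornithine aminotransferase gene Oat, a pericentral gene, was 3.48-fold higher (3.43 to 3.53), 2.93-fold higher (2.89 to 2.98) and 3.29-fold higher (3.25 to 3.34) in the Cyp27a1 KO, Cyp3a KO and DKO against WT. Pericentral genes had medians of 0.05, 0.23 and -0.25 and periportal genes of -0.27, -0.27 and -0.39 in the same order. In the DKO, the NRF2 targets were higher in 7 of 11 cases (median 1.73, percentile 100), with Srxn1 at a log2 fold of 1.73, and Hmox1 at -0.10; in the Cyp3a KO Hmox1 was 2.33-fold lower (2.13 to 2.56), 3 were higher and 1 lower (median 0.31).

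LXR targets had medians of -0.18, 0.05 and 0.19 in the Cyp27a1 KO, Cyp3a KO and DKO against WT, although the phospholipid transfer protein gene Pltp was 6.58-fold higher (6.14 to 7.06) in the Cyp27a1 KO and Abcg1 2.25-fold higher (1.89 to 2.69) in the DKO. Lipoprotein genes had medians of -0.16, -0.22 and -0.22, with Apoa4 2.50-fold lower (2.42 to 2.58) and 4.59-fold lower (4.41 to 4.78) in the single knockouts. Fasting genes had medians of 0.08, -0.68 and -0.66 (percentiles 64.84, 0 and 0.15). The insulin-like growth factor binding protein gene Igfbp1 was 2.28-fold lower (2.24 to 2.32) in the Cyp3a KO. FXR targets had medians of 0.70 in the Cyp3a KO and 0.69 in the DKO (percentiles 99.68 and 99.05), with 1 of 5 past the rule in each. On deposited TPM 2 of 6 were higher and 1 lower in the Cyp3a KO and 3 of 6 higher in the DKO. Acute phase genes had medians of -0.12, -0.37 and -0.42 (percentiles 2.09, 0 and 0.06), with Saa1 2.97-fold lower (2.75 to 3.22) in the Cyp3a KO and Orm3 11.3-fold higher (9.40 to 13.7) in the DKO. Nuclear receptor genes had medians of -0.14, -0.06 and -0.22, with the estrogen receptor gene Esr1 2.76-fold higher (2.44 to 3.12) in the DKO.

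Interferon response genes were higher in 1 of 15 cases in the Cyp27a1 KO (median 0.50, percentile 100) and in 3 of 15 in the Cyp3a KO (median 0.63, percentile 100). Medians of the p53 targets were -0.15, 0.07 and 0.01, of mitochondrially encoded genes -0.07, 0.11 and 0.17, and of hepatocyte secreted proteins -0.13, -0.29 and -0.25 across the 3 knockouts. Recruited macrophage markers had medians of 0.30, -0.43 and 0.02, with 4 measured. Of the remaining cell types few markers were measured: 2 of B and plasma cells (medians 0.68, 0.16 and 1.06), 1 of neutrophils, Csf3r (2.67-fold higher (1.85 to 3.94) in the DKO, and below the filter on deposited TPM), 1 of pancreatic acinar cells, Cela1 (log2 folds -0.89, -0.07 and -0.91), and 2 of adipocytes (medians -0.75, -1.45 and -1.87). In the Cyp3a KO and DKO, endothelial markers had medians of -0.21 and -0.12, stellate and matrix genes -0.00 and -0.39, and cholangiocyte markers -0.19 and -0.11. Nnt, the strain marker, had log2 folds of 0.07, 0.06 and 0.30 in the Cyp27a1 KO, Cyp3a KO and DKO against WT.

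Chosen after their values were seen, 3 predicted pseudogenes side by side on chromosome 1 differed sharply: Gm10925 had 54772, 39612, 129 and 35072 counts in WT, Cyp27a1 KO, Cyp3a KO and DKO, Gm28661 had 37416, 54376, 0 and 30737, and Gm28437 had 1478, 2034, 0 and 230. Rpl10-ps1 had 1484 counts in the DKO and 0 in the other 3 libraries. Pseudogenes can share reads with genes of near-identical sequence, so these counts are uncertain. The cause of the differences was not tested.

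Genes past the rule the same way in both pairs of a loss might lie near the deleted locus if strain sequence linked to it were the cause, and a share within 20 Mb of at least 3 times that of all measured genes was set in advance as the mark. For Cyp3a, 2 of 146 genes lay within 20 Mb, a ratio of 0.816 (exact binomial interval 0.099 to 2.895) with 2.45 expected, which argues against linked sequence as the cause of these genes as a set. For Cyp27a1, 6 of 176 genes (Erbb4, Gm6136, Serpine2, Ugt1a5, Ugt1a9 and Wdfy1) did, a ratio of 2.131 (0.788 to 4.546) with 2.82 expected. That ratio was below the mark set in advance, but its interval includes 3, so linked sequence near Cyp27a1 cannot be told apart from genotype for these 6 genes.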
